A study of Mus musculus with 4 samples.

How the data were processed

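The series measured gene expression in mouse hearts with single-colour Affymetrix arrays, hybridised with biotin-labelled cRNA made from Trizol-extracted total RNA. Per the labels, the 4 arrays hold heart RNA of C57B6 mice aged 3.6 months, without treatment, of 2 genotypes with 2 arrays each. One group was wild-type, and the other carried a knock-in that replaces serine 21 of the kinase GSK-3α with alanine. The deposited values are RMA summaries on the log2 scale, 1 per probe set and array, made in Affymetrix Expression Console per the submitters' processing notes. RMA corrects the background, forces the arrays to 1 distribution and summarises the probes of each probe set, so a difference shared by most genes is removed. Per the labels, the wild-type arrays were normalised with the knock-in arrays alone for this comparison, and the same scans were normalised a second time elsewhere, for another comparison not analysed here. The program's version and any filter are not given in the sources used here. Raw scans were not used here.

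The table held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested. Gene names came from the array's annotation table: 34945 tested probe sets had 1 gene symbol, 932 had several and 9160 had none listed. No gene was named from a probe set with several symbols, which leaves out Cpt1b and Ddx3y. Of 18194 genes, 18032 were matched by gene ID to a mouse gene table of assembly GRCm38.p6, used only for names and for the order of neighbouring genes. Each gene was represented by its probe set with the highest mean over the 4 arrays. The choice uses no group labels, but a probe set higher in 1 group gains mean and can be chosen for that reason.

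Differences are knock-in minus wild-type. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom per probe set, to which the fitted prior added 4.54. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists of pathways and cell type markers. Camera was repeated with the correlation estimated from the data, where its test rests on the 2 residual degrees of freedom. Fry was also run, which answers another question, whether a list moves at all and not whether it moves against other genes. It rests on the same 2 degrees of freedom. After adjustment over 42 lists neither could readily call a list, so a missing call there is weak evidence. Of 954 list entries, 879 had a probe set with 1 symbol. The count of members past the test is given over all probe sets and, separately, adjusted over the list alone. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

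The groups, tests, lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 12 genes per direction past the test and with no overlap between the groups. Where fewer than 10 pass, it fills to 10 per direction with the genes of smallest limma p and a mean log2 value of at least 6, which are then described as not past the test. A set of heart, fuel-use, GSK-3 and sex-linked genes is always named, and so are up to 4 members of each list described. A list of liver markers was added after the values had been seen.

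The fit was tested on 10 simulated data sets of 45037 probe sets, with variances drawn from the fitted prior and independent normal noise. In each, 200 genes were changed, by log2 values of 1, 2 or 4. The fit recovered 64.9% of probe sets changed by 1, 98.1% of those changed by 2 and 99.8% of those changed by 4, and it called 0.0219% of unchanged ones. With 200 changed genes the adjusted threshold is easier to pass than with the 3 probe sets called in the data. These shares therefore overstate the power in the data. Lists were simulated on 18194 genes that vary independently, so the effect of correlated genes was not simulated. Of lists shifted by 0.05, 0.1, 0.2, 0.3 and 0.5, 2.5%, 22.5%, 95%, 100% and 100% were recovered, and 0.293% of unshifted lists were called. The number of arrays limits the precision: the median standard error of a log2 difference was 0.12. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples only, which may be technical. No slide or scan batch was given in the sources used here. The alternatives covered the prior variance, dim and cross-hybridising probe sets, the normalisation between arrays, array weights, the replicate number as a block, each array left out in turn, the threshold, and how probe sets and gene lists are summarised.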

Results

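The data are genome-wide transcript levels on 4 arrays of mouse heart RNA at baseline, 2 of wild-type hearts and 2 of hearts from mice in which serine 21 of GSK-3α is replaced by alanine, a site through which Akt and related kinases restrain this enzyme. The comparison asks which cardiac transcripts differ when GSK-3α cannot be restrained at this site. The labels do not say that each array holds a separate animal, so n below counts arrays. Array medians lay between 6.14 and 6.23 on the log2 scale. The 3′ minus 5′ log2 signal of the control probe sets, a sign of RNA quality, was highest on knock-in replicate 2. For Gapdh it was 0.76 there, against 0.62 and 0.61 on wild-type replicates 1 and 2 and 0.54 on knock-in replicate 1. For actin it was 0.51, against 0.41, 0.41 and 0.38. The array's control probe set for B1 repeats differed by genotype, at 11.49 and 11.60 in wild-type against 12.27 and 12.10 in knock-in hearts. Arrays did not separate cleanly by genotype: the SD of the log2 difference was 0.24 between the wild-type arrays and 0.21 between the knock-in arrays, against 0.23 between wild-type replicate 2 and knock-in replicate 2. Wild-type replicate 1 stood farthest from the knock-in arrays, with SDs of 0.31 and 0.31.

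Gsk3a itself, the targeted gene, had a lower mean in the knock-in hearts, at 10.71 ± 0.13 (SD, n = 2) against 11.12 ± 0.06 (SD, n = 2) in wild-type. Its log2 difference was −0.42 with a standard error of 0.12 and a 95% interval from −0.70 to −0.14, and it did not pass the test over all probe sets (limma adjusted p = 0.458). Each knock-in value (10.62 and 10.80) lay below each wild-type value (11.16 and 11.08). The groups did not overlap, in either direction, for 46.5% of all genes, against 33.3% expected by chance, so this alone says little. A single amino acid substitution need not alter transcript level, and only 1 probe set measures the gene, so this is no firm check of the labels. The sister kinase gene Gsk3b differed by −0.09 (95% interval −0.39 to 0.21) by its representative probe set, and its other probe sets lay between −0.45 and 0.06.

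Of the genes tested, 2 rose and 0 fell. Cap1, which encodes an actin-regulating protein, rose from 5.15 ± 0.35 (SD, n = 2) to 9.82 ± 0.13 (SD, n = 2). Its log2 difference was 4.67 with a standard error of 0.18 (limma adjusted p = 0.0032), and a second Cap1 probe set rose by 4.09 (adjusted p = 0.0033). Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 5.63 ± 0.05 (SD, n = 2) to 7.55 ± 0.06 (SD, n = 2), with a log2 difference of 1.92, a standard error of 0.11 and an adjusted p of 0.0128. Both wild-type means lay below the array medians and may hold mostly background, so no fold is given for these 2 genes or for others as dim. Limma called 3 probe sets higher and 0 lower, whereas 2283 were higher and 2530 lower at an unadjusted p under 0.05, with 2252 in all expected by chance. Cap1 lost its call without knock-in replicate 1 (adjusted p = 0.261) or replicate 2 (0.0516), and Cyp1a1 lost its call whichever array was left out (0.114 to 0.278) while their differences stayed between 4.42 and 4.91 and between 1.88 and 1.97. Shifting the arrays to 1 median, or averaging each gene's probe sets, raised the count to 6 or 7 genes, and Gm38983, not called here (adjusted p = 0.0606), passed in 6 settings. Leaving out probe sets with a mean below 7 lowered the count to 1, Cap1, since Cyp1a1 is then not tested. With the replicate number as a block Cap1 was called (limma adjusted p = 0.0421) and Cyp1a1 was not.

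**Figure D1:**
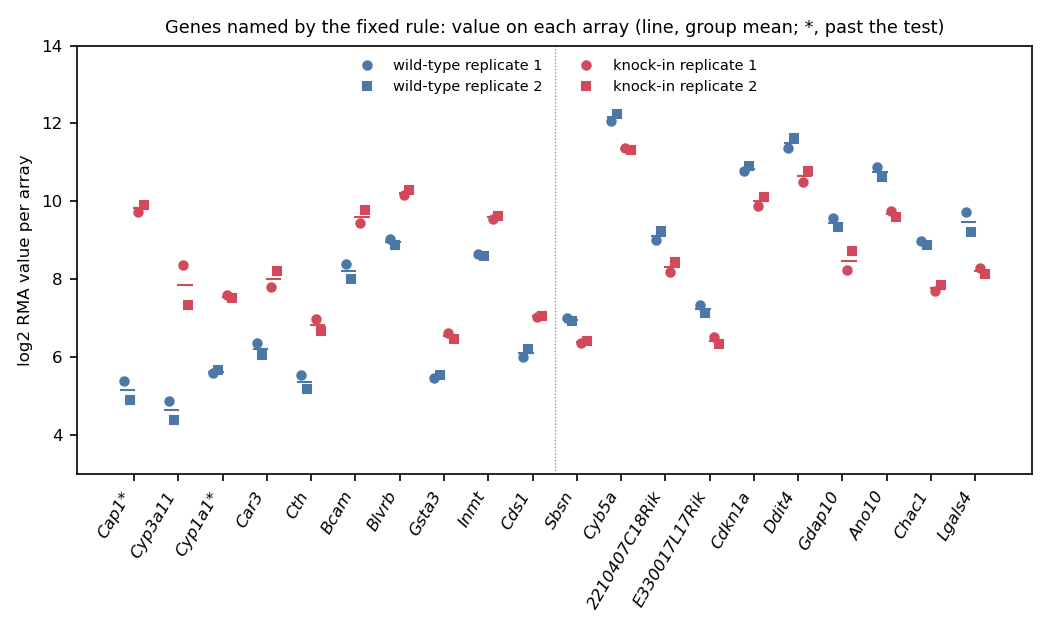
Log2 RMA value on each of the 4 arrays for 10 genes higher and 10 lower in the knock-in hearts, picked by the fixed rule (past the test, then smallest p); lines mark group means and an asterisk marks genes past the test. Cap1 and Cyp1a1 carry the asterisk, and Cyp3a11 shows the widest gap between the knock-in arrays (8.37 and 7.34).

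The following genes had the next smallest p among those higher in the knock-in hearts, and none passed the test. Blvrb, which encodes biliverdin reductase B, was 2.41-fold higher (limma adjusted p = 0.153), and the glutathione transferase gene Gsta3 differed by 1.04 (0.161), against 0.60 by its other probe set. Cyp3a11, a cytochrome P450 abundant in liver, differed by 3.22 (0.153) from wild-type values of 4.89 and 4.39, and Cth, which makes cysteine from cystathionine, by 1.45 (0.198). The methyltransferase gene Inmt was 1.96-fold higher, the laminin receptor gene Bcam 2.64-fold higher while Cds1, of phospholipid synthesis, differed by 0.94, against 0.35 by its other probe set. The carbonic anhydrase gene Car3 differed by 1.79 by its brightest probe set, while its 3 other probe sets differed by −0.00, 0.04 and 0.26. In all, 51 genes were at least 2-fold higher and 3 at least 2-fold lower by RMA values, regardless of the test and of their level. The higher genes include liver markers described below, such as Alb at 3.71 and Fabp1 at 3.06.

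Among genes lower in the knock-in hearts none passed the test, and those of smallest p follow. Chac1, a glutathione-degrading enzyme gene induced through ATF4, was 2.24-fold lower (log2 difference −1.17, limma adjusted p = 0.153). Ddit4, an inhibitor of mTORC1 signalling, differed by −0.86 (0.329), and the cell cycle inhibitor gene Cdkn1a by −0.83 (0.283). Lgals4, which encodes a galectin, was 2.40-fold lower and Ano10 2.10-fold lower, with log2 differences of −1.26 and −1.07. Lgals4, like Blvrb and Bcam, lies on chromosome 7 among the 100 measured genes on each side of Gsk3a. The cytochrome b5 gene Cyb5a differed by −0.80, and Gdap10, E330017L17Rik, 2210407C18Rik and Sbsn lay between −0.97 and −0.57, against −0.54 and −0.02 by the other Sbsn probe sets.

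Transcripts typical of liver were higher in the knock-in hearts, which is given here as a measured fact because it accompanies every group described. Of 61 liver markers, a list added after the values had been seen, 58 were higher, with a median log2 difference of 0.81. Adjusted over the list alone, 33 rose and 0 fell, whereas over all probe sets 0 passed. Albumin (Alb) differed by 3.71, the fibrinogen chain gene Fga by 3.26, the liver fatty acid binding protein gene Fabp1 by 3.06 and the apolipoprotein gene Apoa1 by 2.78. The knock-in arrays were unequal, with marker medians of 7.22 in replicate 1 and 6.24 in replicate 2, against 5.61 and 5.44 in the wild-type arrays. The camera p of the list was 4.45e-25, and p = 0.201 with an estimated correlation.

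**Figure D2:**
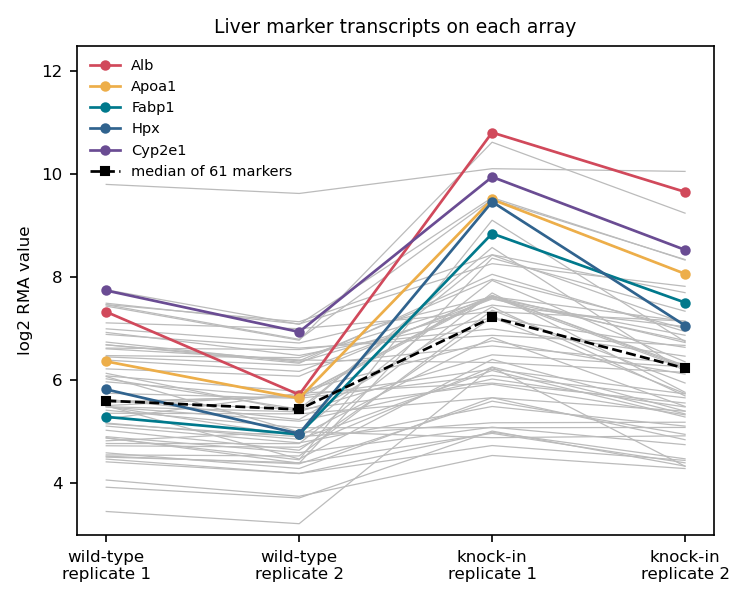
Log2 RMA values of 61 liver marker genes on each array, 1 grey line per gene, with 5 genes coloured and the median dashed. The median is 5.61 and 5.44 on the wild-type arrays and 7.22 and 6.24 on the knock-in arrays.

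Genes of fatty acid use and targets of the lipid-sensing receptor PPARα bear on a question for which GSK-3α is studied in the heart, and none of these 3 lists shifted past the test. Of 22 measured genes of mitochondrial fatty acid oxidation, 14 were higher and 8 lower, with a median of 0.01 and a mean of −0.02 (camera adjusted p = 0.895); the direction of the test turned to higher when arrays were shifted to 1 median. Acot2 differed by −0.38, Ech1 by −0.26, Cpt2 by −0.10 and Acadm, the medium-chain acyl-CoA dehydrogenase gene, by 0.10. Of 24 PPARα target genes, 9 were higher and 15 lower, with a median of −0.03 (adjusted p = 0.267, against 0.0237 over probe sets with a mean of at least 7 and 0.0414 after cyclic loess, a setting added after seeing the data). Acot1 and Acot2 each differed by −0.38, Fgf21 by −0.40 and Txnip by −0.52. Among 24 genes of fatty acid uptake, activation and storage the median was 0.08 (adjusted p = 0.189), with Acsl4 at 0.65, Acsl6 at 0.45, G0s2 at 0.37 and the lipase gene Lipe at −0.34. With 1 array left out these single differences could shrink, to 0.26 for Acsl4 and 0.27 for Acsl6 without wild-type replicate 1, −0.22 for Lipe and −0.05 for Cpt2 without knock-in replicate 1, and −0.28 for Txnip without knock-in replicate 2. No member of the 3 lists passed over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05, 3 were higher in the uptake list, and 2, 4 and 1 were lower in the respective lists. The receptor gene Ppara differed by 0.06 (95% interval −0.20 to 0.32), the fatty acid transporter gene Cd36 by 0.13 (−0.13 to 0.39), Fabp3 by 0.10 (−0.15 to 0.35), Pdk4 by −0.06 (−0.33 to 0.20) and Ucp3 by −0.02 (−0.35 to 0.31). The sign for Ppara turned after quantile normalisation or cyclic loess, and that for Ucp3 with arrays shifted to 1 median; averaging each gene's probe sets turned Ppara, Ucp3 and Fabp3. Other probe sets had the opposite sign for Ppara (−0.06 and −0.12), Ucp3 (0.04), Fabp3 (−0.45) and Cd36 (−0.09, with another at 0.12). For Acsl4 the other probe sets lay at 0.13 and −0.04, for Acsl6 at 0.15, for Acot2 at −0.03, for Lipe at 0.07 and for Cpt2 at 0.32.

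Lists of glucose and glycogen handling shifted upward by small amounts, alongside the liver-marker difference of 0.81. Of 19 genes of glycogen metabolism 17 were higher, with a median of 0.16 (camera adjusted p = 0.0109, and adjusted p = 0.693 with an estimated correlation). Adjusted over the list alone, 1 rose, the liver-type glycogen phosphorylase gene Pygl at 0.82, and over all probe sets 0 did, with 3 higher and 0 lower at an unadjusted p under 0.05. Gbe1, Phkb and Ugp2 lay at 0.51, 0.33 and 0.25. Of 20 genes of glucose uptake and glycolysis 17 were higher, with a median of 0.11 (adjusted p = 0.0153, and adjusted p = 0.693 with an estimated correlation). Adjusted over the list alone, 1 rose, Pfkfb2 at 0.72, whose product makes the glycolytic activator fructose 2,6-bisphosphate, and over all probe sets 0 did. Pfkp lay at 0.34 and Pgam2 at 0.27, while the transporter genes Slc2a1 and Slc2a4 differed by −0.29 and 0.21. Among 26 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase 21 were higher, with a median of 0.06, Dld at 0.31 and Pdhx at 0.22 (adjusted p = 0.041, and adjusted p = 0.693 with an estimated correlation). No member of that list passed in either adjustment, with 0 at an unadjusted p under 0.05. Without knock-in replicate 2 these 3 calls were lost at adjusted p between 0.0584 and 0.0832, and cyclic loess normalisation ended them at 0.0633 to 0.745. The glycolysis call was also lost without wild-type replicate 2 (0.128), and the tricarboxylic acid cycle call without any 1 array (up to 0.156). Of 16 camera settings the glycogen, glycolysis and tricarboxylic acid cycle calls held in 12, 10 and 6. Without wild-type replicate 1 Gbe1 lay at 0.31, Phkb at 0.21 and Dld at 0.13, and without wild-type replicate 2 Slc2a4 lay at 0.14. Other probe sets lay between −0.03 and 1.14 for Pfkfb2, at 0.49 and −0.10 for Pfkp, at −0.12 for Dld, at −0.09 and −0.11 for Slc2a1 and at 0.13 for Slc2a4.

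The mitochondrial biogenesis and lipid synthesis lists also shifted upward, beside the same liver-marker difference. Of 21 genes of mitochondrial biogenesis and dynamics 16 were higher, with a median of 0.15, Esrrb at 0.37, the fission gene Dnm1l at 0.32 and Nrip1 at 0.29 (camera adjusted p = 0.0197, and adjusted p = 0.693 with an estimated correlation). The coactivator gene Ppargc1a differed by −0.21 (95% interval −0.46 to 0.05), and its other probe sets lay between −0.11 and 0.12. Of 24 genes of cholesterol and fatty acid synthesis 15 were higher, with a median of 0.08, Cyp51 at 0.57, Scd1 at 0.48 and Insig1 at 0.45 (adjusted p = 0.0197, and adjusted p = 0.693 with an estimated correlation). In both lists 0 members passed over all probe sets or adjusted over the list alone, with 3 and 5 higher at an unadjusted p under 0.05. Both calls were lost without knock-in replicate 2 (0.0721 and 0.0675), without wild-type replicate 1 (0.127 and 0.0668), with the mean of each gene's probe sets (0.154 and 0.0809) and after cyclic loess (0.38 and 0.115). Each held in 8 of 16 camera settings, and Cyp51 lay at 0.28 without wild-type replicate 1. Other probe sets lay between −0.16 and 0.14 for Esrrb, −0.11 and 0.09 for Dnm1l, −0.14 and 0.35 for Nrip1 and 0.02 and 0.54 for Cyp51, and at 0.15 for Scd1.

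Protein turnover genes were higher by similarly small amounts, again with the liver markers at 0.81. Of 30 proteasome subunit genes 27 were higher, with a median of 0.12, Psmc1 at 0.35, Psmd12 at 0.33 and Psmd7 at 0.32 (camera adjusted p = 0.000389, and adjusted p = 0.693 with an estimated correlation). Of 29 autophagy and lysosome genes 22 were higher, with a median of 0.09, Hexa at 0.34, Pik3c3 at 0.23 and Becn1 at 0.22 (adjusted p = 0.0231, and adjusted p = 0.693 with an estimated correlation). In the circadian clock list 11 of 17 genes were higher, with a median of 0.34, and Dbp, a clock output gene, lay at 0.88, Cry1 at 0.47 and Nr1d2 at 0.44 (adjusted p = 0.0109, and adjusted p = 0.693 with an estimated correlation). In these 3 lists 0 members passed over all probe sets or adjusted over the list alone, with 4, 1 and 6 higher at an unadjusted p under 0.05. All 3 calls were lost without knock-in replicate 2 (0.0583, 0.0887 and 0.167), and the clock and autophagy calls also without wild-type replicate 2 (0.0991 and 0.0716). The autophagy call was lost without wild-type replicate 1 (0.0785) and, with the proteasome call, after cyclic loess (0.745 and 0.0633). Of 16 camera settings the proteasome, autophagy and clock calls held in 13, 8 and 12, and without wild-type replicate 2 Dbp lay at 0.47 and Nr1d2 at 0.26. Other probe sets lay between −0.14 and 0.63 for Becn1, at 0.17 and −0.03 for Psmd7 and at 0.12 for Psmc1.

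Interferon response genes shifted downward, while the liver markers were higher by 0.81. Of 24 measured genes 20 were lower, with a median of −0.15, Ifit1 at −0.56, the GTPase gene Igtp at −0.33, and the antiviral genes Rsad2 and Oas1a each at −0.28 (camera adjusted p = 0.0026, and adjusted p = 0.693 with an estimated correlation). No member passed over all probe sets or adjusted over the list alone, and 0 were higher and 6 lower at an unadjusted p under 0.05. The call held without each array in turn (0.000257 to 0.0458) and after cyclic loess (9.96e-06), and among 16 camera settings it was lost only with the estimated correlation. Fry, which asks whether the list moves at all and not whether it moves against other genes, did not call it (adjusted p = 0.46). Immune cell markers were mixed, with 13 of 15 lymphocyte and 9 of 11 neutrophil markers lower, and 11 of 19 macrophage and myeloid markers higher.

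Cell type markers shifted in both directions, beside the liver-marker difference of 0.81. Of 16 fibroblast markers 15 were higher, with a median of 0.19, Smoc2 at 0.37, Serpinf1 at 0.33 and Tcf21 at 0.29 (camera adjusted p = 0.000994, and adjusted p = 0.693 with an estimated correlation). Of 17 endothelial markers 13 were higher, with a median of 0.08, Vwf at 0.48, Aqp1 at 0.31 and Cldn5 at 0.31 (adjusted p = 0.0344, and adjusted p = 0.693 with an estimated correlation). Of 15 lymphocyte markers 13 were lower, with a median of −0.18, Cd79a at −0.35 and Cd2 at −0.34 (adjusted p = 0.0191, and adjusted p = 0.727 with an estimated correlation). Of 15 lung and thymus markers 14 were lower, with a median of −0.11, the surfactant gene Sftpc at −0.30 and Foxn1 at −0.34 (adjusted p = 0.0344, and adjusted p = 0.706 with an estimated correlation). In these 4 lists 0 members passed over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05, 3 fibroblast and 3 endothelial markers were higher, and 1 lymphocyte and 2 lung or thymus markers lower. All 4 calls were lost without knock-in replicate 2 (0.0585 to 0.368), the fibroblast and endothelial calls without wild-type replicate 2 (0.05 and 0.287), and the lymphocyte and lung calls without wild-type replicate 1 (0.279 and 0.22). After cyclic loess the fibroblast call held (0.0304) and the other 3 were lost (0.105 to 0.512). The fibroblast, endothelial and lymphocyte calls held in 13, 9 and 10 of 16 camera settings. The lung and thymus call held in 10 of 15, as too few of its members had a mean of at least 7 for that setting. Sftpc, Foxn1, Cd79a and Cd2 had mean log2 values between 5 and 7, a range in which the median difference of all probe sets was −0.10. The lung and thymus median of −0.11 therefore does not stand apart from that of dim probe sets in general. After cyclic loess it was −0.03, and the lymphocyte median was −0.11. Single differences shrank to 0.20 for Smoc2 and Vwf without knock-in replicate 2, 0.22 for Serpinf1 without wild-type replicate 2, −0.20 for Cd79a and −0.15 for Cd2 without wild-type replicate 1, and −0.16 for Foxn1 without knock-in replicate 1. The other probe set of Tcf21 lay at −0.15 and that of Serpinf1 at 0.05.

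Across the 42 lists camera called 10 higher and 3 lower, whereas 0 were called with an estimated correlation, with 0 at an unadjusted p under 0.05. Fry, which tests a list against no change and not against other genes, called 0, with 6 at an unadjusted p under 0.05. Both of these tests rest on 2 residual degrees of freedom and could hardly call any list. Their 0 calls therefore do not decide whether the lists shifted. Without knock-in replicate 2, 1 list was called, from the original 13; without wild-type replicate 2, 8 were (7 from the 13), without wild-type replicate 1, 10 (7) and without knock-in replicate 1, 17 (12). Over probe sets with a mean of at least 5, 7 lists were called (7 from the 13), with a mean of at least 7, 6 (3), after repeated quantile normalisation 8 (6), after cyclic loess 6 (3) and with the mean of each gene's probe sets 15 (11). The cell cycle list, not among the 13 (camera adjusted p = 0.2345), was called higher after repeated quantile normalisation (0.0136) and after cyclic loess (0.0109). Of 172 members taken from the lists, up to 4 per list, 72 had a difference that moved by over 1.5 times with 1 array or another left out. These were 166 different genes, of which 88 had another probe set and 38 had one of opposite sign. These shifts stand beside the liver markers at 0.81 and the B1 repeat control, which was also higher in both knock-in arrays. The liver-marker median was larger on knock-in replicate 1 (7.22) than on replicate 2 (6.24), whereas more list calls were lost without replicate 2. An effect of liver RNA on the lists was not tested. Knock-in replicate 2 also had the highest 3′ minus 5′ control signals of the 4 arrays. The median difference of probe sets depended on brightness: it was −0.09 below a mean log2 value of 5, −0.10 from 5 to 7, 0.04 from 7 to 9, 0.08 from 9 to 11 and 0.05 above 11.

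**Figure D3:**
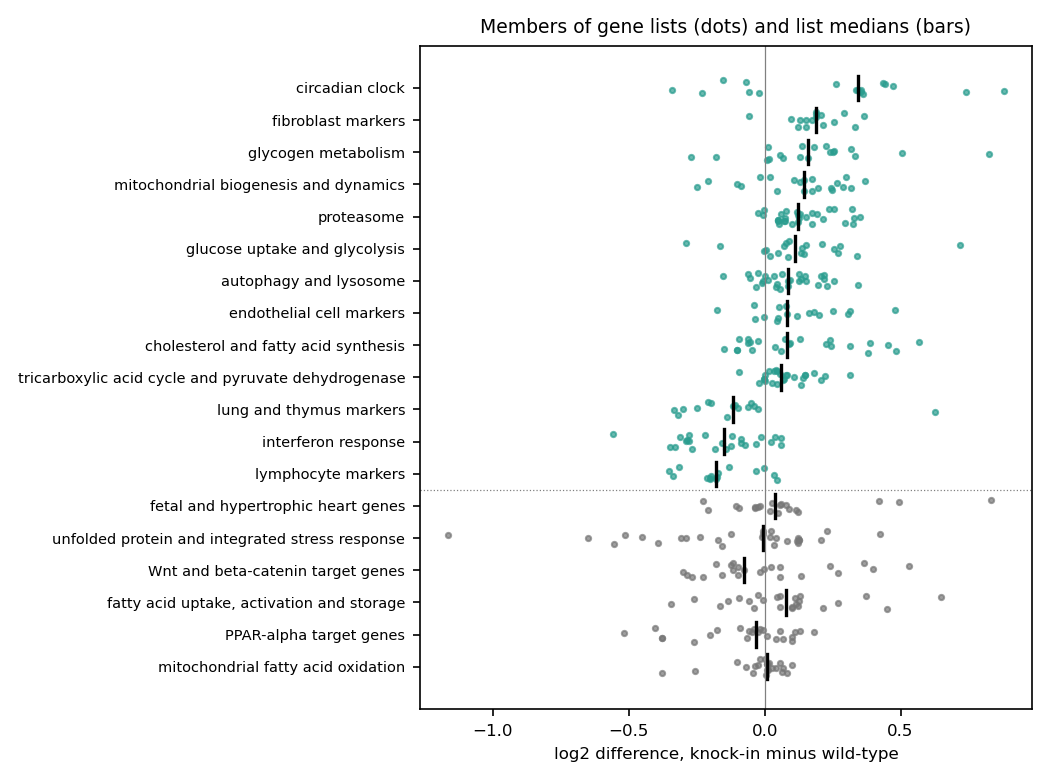
Log2 difference, knock-in minus wild-type, of each measured member (dots) with list medians (bars), for the 13 called lists above the dotted line and 6 further lists below it. Circadian clock genes have the highest median (0.34) and lymphocyte markers the lowest (−0.18).

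Markers of cardiac remodelling gave mixed values. Myh7, the slow myosin heavy chain of the fetal heart programme, was 1.78-fold higher (log2 difference 0.83, 95% interval 0.48 to 1.18, limma adjusted p = 0.36), and skeletal actin (Acta1) was higher by 0.49 (0.17 to 0.82). The natriuretic peptide genes Nppa and Nppb differed by −0.02 and 0.05, both signs turning under another scaling, with 95% intervals from −0.28 to 0.24 and from −0.42 to 0.52. Myh6 differed by 0.10 (−0.16 to 0.36), and by 0.45 by its other probe set. Of 20 fetal and hypertrophic genes 12 were higher, with a median of 0.04, and the direction of the test turned after cyclic loess (camera adjusted p = 0.266). Adjusted over the list alone, 1 rose, Myh7, and over all probe sets 0 did, with 3 higher and 0 lower at an unadjusted p under 0.05.

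Targets of β-catenin, a protein that GSK-3 marks for degradation, did not move together. Of 23 measured genes 9 were higher and 14 lower, with a median of −0.08 and a mean of 0.00, and the direction of the test turned to higher after quantile normalisation or cyclic loess (camera adjusted p = 0.938). Sfrp2 differed by 0.53, Ccn5 by 0.40, Dkk3 by 0.37 and Ccnd1 by 0.24 (95% interval −0.02 to 0.50; other probe sets −0.02 and 0.34), with Sfrp2 at 0.27 without wild-type replicate 2. Axin2 differed by 0.13 (−0.15 to 0.42), against −0.20 by its other probe set, Myc by −0.12 (−0.45 to 0.20) and Ctnnb1, which encodes β-catenin, by 0.03 (−0.23 to 0.29), with its sign turning after quantile normalisation or cyclic loess and its other probe sets at 0.29 and 0.19. No member passed over all probe sets or adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05.

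Genes that can mark substrain or sex were measured as checks. Nnt, which carries a deletion in the C57BL/6J substrain, was bright on all arrays by its brightest probe set, at 12.97 ± 0.22 (SD, n = 2) in wild-type and 13.30 ± 0.08 (SD, n = 2) in knock-in hearts, and the other Nnt probe sets differed by 1.02 and −0.12. Whether these probe sets lie inside the deleted part is not known here, so they check nothing. Kdm5d, Eif2s3y and Uty, on the Y chromosome, differed by 0.35, 0.30 and 0.09, with Kdm5d at 0.21 and Uty at −0.02 without wild-type replicate 1. The other probe sets lay at −0.30 and −0.26 for Kdm5d, at 0.09 for Eif2s3y and between −0.24 and 0.51 for Uty. Xist differed by −0.30 (95% interval −0.58 to −0.02) by its brightest probe set and by −0.07 and 0.01 by its other probe sets. On all 4 arrays Eif2s3y lay between 8.17 and 8.57, and the other Xist probe sets lay between 3.54 and 3.98. By these levels no array stood apart by sex.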

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

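Cyclic loess between the arrays and the lists without liver markers were chosen after seeing the data, and the other settings were planned. The count of 3 probe sets became 5 at an adjusted p under 0.10, 1 with means of at least 7 (fewer probe sets tested), 11 with arrays shifted to 1 median, and 0 to 2 with an array left out. The count of 2 genes became 3, with Gm38983 added, under the intensity trend in the prior, the robust prior, means of at least 5 and array weights, 3 at an adjusted p under 0.10, 1 with means of at least 7, 6 with arrays shifted to 1 median, 7 (6 higher, 1 lower) with the mean of a gene's probe sets, and 0 to 1 with an array left out (fewer samples, the lone sample being assumed to vary like the other group). The 13 lists became 7 and 6 with means of at least 5 and 7, 8 after repeated quantile normalisation, 6 after cyclic loess, 15 with the mean of probe sets (11 from the 13, without mitochondrial biogenesis at 0.154 and cholesterol synthesis at 0.0809, and with oxidative phosphorylation at 0.0135, sarcomere at 0.0159, heat shock at 0.0371 and branched-chain amino acids at 0.0345), 0 with an estimated correlation, 0 with fry (which tests against no change and not against other genes), and 1 to 17 with an array left out. No fixed list held a gene of the added liver-marker list, although the glycogen list holds Pygl, the liver-type glycogen phosphorylase gene. With the markers also left out of the genes the lists are compared with, the same 13 lists were called. As no list lost a member, this outcome was nearly fixed beforehand. It does not test an effect of mixed RNA on other genes. Camera has no robust prior, so that setting gives no value for the lists. The labels give both groups the numbers 1 and 2, and do not say whether same-numbered arrays belong together. Their deviations correlated at 0.0848, but 2 pairs cannot decide this. At an unadjusted p under 0.05 the split by replicate number held 1166 probe sets and the crossed split 614. With the number as a replicate block the counts were 4 probe sets, 2 genes (Cap1 and Alb) and 12 lists. Cyp1a1 was then not called, at a limma adjusted p of 0.104. The Gsk3a difference kept its sign and its side of the threshold in every setting run, from −0.51 to −0.33. Among 42 named genes, 587 of 621 values under other settings kept direction and side, 7 lost and 6 gained a call, and 21 turned sign, 9 of them with an array left out. The gains were Blvrb, Car3 and Cyp3a11 with arrays shifted to 1 median and Blvrb, Inmt and Chac1 with the mean of probe sets. Signs turned as follows: with the mean of probe sets Axin2 was −0.034, Fabp3 −0.18, Ppara −0.040 and Ucp3 0.0089; after cyclic loess Ctnnb1 was −0.027, Nppb −0.0036 and Ppara −0.020; after repeated quantile normalisation Ctnnb1 was −0.029 and Ppara −0.024; with arrays shifted to 1 median Nppa was 0.043 and Ucp3 0.043; and Xist was 0.0055 without cross-hybridising probe sets. With an array left out the range was −0.024 to 0.082 for Ctnnb1, −0.19 to 0.021 for Gsk3b, −0.27 to 0.024 for Myc, −0.073 to 0.037 for Nppa, −0.25 to 0.34 for Nppb, −0.0033 to 0.12 for Ppara and −0.14 to 0.11 for Ucp3. Except where stated, the cause was not tested. Dim probe sets limit the comparison, since background compresses differences there.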

Other observations

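All tests of an explanation in this part were chosen only after the result was seen. Genes of the unfolded protein and integrated stress response fell in part: adjusted over the list alone, 3 of 28 fell (Chac1 at −1.17, the chaperone gene Hyou1 at −0.51 and Sdf2l1 at −0.65) and 0 rose, while over all probe sets 0 passed. The list median was −0.01 and camera did not call it (adjusted p = 0.132), although it did without wild-type replicate 1 (0.000386), over probe sets with a mean of at least 7 (0.000439) and after cyclic loess (0.0109). Without wild-type replicate 2 its adjusted p was 0.796. Among 19 hypoxia response genes, adjusted over the list alone, 2 rose (Hif1a at 0.94 and Ankrd37 at 0.52) and 2 fell (Ddit4 at −0.86 and the haem oxygenase gene Hmox1 at −0.42), and over all probe sets 0 passed (camera adjusted p = 0.238). In the list of FoxO targets 1 fell adjusted over the list alone, Cdkn1a at −0.83, and in the list of Nrf2 targets 1 rose, Gsta3 at 1.04, with camera adjusted p of 0.836 and 0.565 and 0 members past the test over all probe sets in either.

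Muscle and connective tissue lists held single genes apart from their list. Adjusted over the list alone, 2 of 19 skeletal muscle markers rose, Myot at 0.93 and Myl1 at 0.46, although the list median was −0.06 and its mean 0.03 (camera adjusted p = 0.786); over probe sets with a mean of at least 7 the list was called higher (0.0077). One fat marker, Car3 at 1.79, rose adjusted over the list alone (adjusted p = 0.112 for the list), while its other probe sets differed by −0.00, 0.04 and 0.26. Col14a1 differed by 0.58 in the matrix list (adjusted p = 0.415). Over all probe sets 0 members of these 3 lists passed. The list of oxidative phosphorylation genes had 37 of 52 members higher with a median of 0.03 (adjusted p = 0.234), a direction that turned after cyclic loess; with the mean of each gene's probe sets camera called it higher (0.0135). Gm38983, chosen after its values were seen, differed by 2.05 from dim wild-type values of 4.46 and 4.87 (limma adjusted p = 0.0606); it passed in 6 settings, with the intensity trend in the prior (0.0327), the robust prior (0.0422), means of at least 5 (0.0441), arrays shifted to 1 median (0.0274), array weights (0.0373) and the mean of probe sets (0.0134).

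Liver transcripts were higher as a group in the knock-in hearts. Liver RNA mixed into the knock-in samples in unequal amounts is a candidate source: 94.6% of the 56 markers not seen before the list was written were higher, and all 36 markers with an unadjusted p under 0.05 had the larger value in knock-in replicate 1. On the wild-type arrays 5 of 61 markers lay at 7 or above, and 56 of 61 were higher in replicate 1 than in replicate 2. The excess in knock-in replicate 2 was a median of 27.8% of that in replicate 1 (central 95% of markers, 12.7% to 63.3%). Cap1, at 115%, and Cyp1a1, at 92.2%, lay outside that range, which argues against this source for both. Blvrb (118%), Inmt (110%), Bcam (147%), Cds1 (102%), Car3 (150%), Pygl (145%), Gsta3 (81.3%) and Cth (70.8%) lay above it too. Orm1 (0.961%) lay below it. Its dim value on knock-in replicate 2 equalled that on wild-type replicate 2 (4.18), against 6.57 on knock-in replicate 1, so it counts neither way. Cyp3a11 (44.8%) lay within the range but is itself a marker, so it tests nothing. Expression of these genes by the hearts themselves was not tested and stays open.

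Genes near Gsk3a on chromosome 7 differed more often than genes elsewhere at some distances: among the 100 measured neighbours on each side 11 had an unadjusted p under 0.01, including Blvrb, Bcam, Lgals4, Trappc6a and Hnrnpl, and 2.18% of all such windows held as many, 102 of these 306 on other chromosomes. At 200 neighbours it was 0.809%, with 0 of 81 on other chromosomes (at most 17 such genes there against 22), but at 50 neighbours it was 16.4%, with 2199 of 2619 on other chromosomes, so chance clustering stays open, a reading settled after the widths had been compared. If the probes match the wild-type strain, which was assumed and not checked, mismatches to a donor allele would lower the knock-in signal. Of the 11 genes 72.7% were higher (exact 95% interval 39.0% to 94.0%). Under that assumption this argues against mismatches as the whole cause. Donor-strain DNA kept around the modified allele may contribute. The share of such genes was 4% among the nearest 100 and 6.5% among the next 200. It was 1.71% in the rest of chromosome 7 and 1.78% on other chromosomes. The nearest 100 genes thus had 2.34 times the share of the rest of the chromosome. How far such DNA would reach is not known here, so the lower share among the nearest 100 does not count against it. Distance therefore shows a local excess but does not settle its source. Cap1, on chromosome 4, had 2 such genes among its 100 nearest, and an effect of the substitution itself on these neighbours was not tested.

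Small shifts of many gene lists may come in part from an intensity-dependent difference between the arrays. After cyclic loess, which removes such a trend, 3 of the 13 called lists were still called in the same direction (interferon response, fibroblast markers and the circadian clock), which argues against the trend as the whole cause for these. The other 10 medians lay closer to 0 after it, by unequal amounts: the autophagy and lysosome median went from 0.09 (quartiles 0.003 and 0.15) to 0.02 (−0.06 and 0.10) and the proteasome median from 0.12 (0.06 and 0.21) to 0.05 (−0.0037 and 0.13), but that of glycogen metabolism only from 0.16 (0.04 and 0.25) to 0.12 (0.03 and 0.22). The fibroblast median went from 0.19 to 0.12 and kept its call, so the size of the move does not by itself say which calls ended. For those 10 lists the trend stays open, as does an effect of genotype. Cyclic loess also added camera calls for lists outside the 13. These were the unfolded protein and integrated stress response (lower, adjusted p = 0.0109), the cell cycle (higher, 0.0109) and PPARα targets (lower, 0.0414).

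The other pairings of the 4 arrays called 0 probe sets, with 1166 and 614 at an unadjusted p under 0.05 against 3 called and 4813 by genotype, and 3 splits are too few for a share under 0.05.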
